A study of Mus musculus with 6 samples.

How the data were processed

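Total RNA from 6 samples of the mouse breast cancer line MTflEcad was depleted of ribosomal RNA, per the labels' protocols. By the same protocols, libraries were sequenced as single 81-base reads. The protocols describe the depletion more than once, with different RNA amounts and kits. The description with 200 ng of RNA and a stranded library kit was taken here. Reads were handled with STAR and the mm10 mouse build, both named without a version in the submitters' processing notes. The gene counter, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited 1 table of CPM (reads of a gene per 1000000 reads assigned to genes) with 24454 gene numbers and 1 column per library. Each column summed to 1000000, so the deposited CPM carry a scaling to the assigned total and no other correction that the values show.

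The 6 columns were assigned to groups by the treatment in the column names and in the sample labels, with 2 libraries each of PBS, I80 and DI150. A DI150 column carries the number 3 while the labels number the DI150 samples 1 and 2. That column was therefore used as a DI150 replicate without a label number of its own, and is called DI150 replicate 3. Gene numbers were matched to a RefSeq gene table of GRCm38.p6, the same build as mm10, which gave symbols and positions for 24374 of them (99.67%). The unmatched genes held 1.21% to 1.52% of the reads of a library, nearly all from gene number 100861531. The table has no gene of the mitochondrial chromosome, and its 49 Y-linked genes are at 0 in every library.

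Within a column, all low values were whole multiples of 1 step, the worth of 1 read, from 0.0376 to 0.0476 CPM. Dividing by that step gave whole reads, within 1e-06 reads, for 100.0% of the 146724 values. Totals of recovered reads ran from 21017849 to 26608715 per library. A gene at 0 reads was given a floor of 3 reads per library, which is 0.113 to 0.143 CPM, and folds against such a group are stated as lower bounds computed from that floor. For a group with 1 to 3 reads in all, the ratio of pooled reads is given with its exact 95% interval. Floors and intervals cover counting error alone, since PCR copies were not told apart.

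The main test was limma 3.58.1 (lmFit, then eBayes with a trend; R 4.3.3) on log2(CPM + 0.5) for the 11428 genes with a mean of at least 1 CPM over the 6 libraries. The 3 groups were fitted together because 2 libraries per group leave 3 residual degrees of freedom, to which the moderated variances added a prior of 4.52. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(CPM + 0.5) scale understate the change of genes at low CPM, so folds are given as ratios of mean CPM. The 3 comparisons were I80 against PBS, DI150 against PBS, and DI150 against I80, which is also the test of whether the effects of the treated lines differ. The replicates are described as biological duplicates, and the sources do not say whether they were separate long-term cultures. The p-values measure the spread between these libraries.

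A set of 36 gene lists was written from textbook knowledge. They covered NRF2 targets, removal of H2O2 and superoxide, production and transport of peroxide, glutathione synthesis, iron handling, p53 targets, DNA repair, the cell cycle, epithelial junctions, mesenchymal genes, extracellular matrix, mammary luminal and basal genes, and markers of fibroblasts, immune cells, endothelium and adipocytes. Further lists held interferon response, MHC class I presentation, NF-kB targets, the integrated stress response, ER chaperones, heat shock, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cholesterol and fatty acid synthesis, TGF-beta and BMP signalling, YAP targets, Wnt targets, ERBB signalling with MAPK feedback, drug efflux and xenobiotic metabolism, ribosomal proteins, noncoding RNAs, immediate early genes, and axon guidance genes. The 30 lists with at least 5 tested members were compared with all other tested genes by limma's camera with its preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the residuals, and fry, were run beside it. fry asks whether the genes of a list move one way on balance and makes no comparison with other genes. Some lists share members, so their calls are not independent. Gpx2, Srxn1 and Prdx1, for example, are in the NRF2 and the peroxide removal lists. Fn1 and Sparc are in the mesenchymal and matrix lists, and Vim and Sparc in the mesenchymal and basal lists. Chromosomes with at least 100 tested genes were tested with camera in the same way.

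Against PBS, the genes named are the 6 with the largest rise and the 6 with the largest fall among called genes with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a predicted-gene name. Between the treated lines, 5 each way were taken. A gene that this rule names is not reported here. Up to 4 called members of each list with the largest change were added, and 12 genes (Cdh1, Epcam, Vim, Zeb1, Hmox1, Nqo1, Cat, Gpx1, Slc7a11, Cdkn1a, Erbb2 and Mki67) were named whatever their result. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined. A replicate block in which DI150 replicate 3 stands for the second DI150 sample was added after seeing the data, and so were some tests of explanations, named where they are given.

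The alternatives were pseudocounts of 0.1 and 1 CPM, no filter and a filter at 5 CPM, median-of-ratios scaling and quantile normalization, eBayes without a trend and with robust variances, a fit on the 4 libraries compared, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. Because whole reads could be recovered from the deposited CPM, the quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0 were run on those reads. edgeR called 7610 genes in I80 against PBS, 7852 in DI150 against PBS and 4997 between the treated lines, of which 7509, 7752 and 4853 were called in the same direction by limma and none in the opposite one. DESeq2 called 7341, 7496 and 4739 genes and gave no adjusted p as missing. For the overlap of the treated lines, 100 sets of unchanged groups were simulated. In each set the PBS libraries were simulated too and shared by both comparisons.

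The steps were tested on simulated reads with planted changes. For I80 against PBS, limma recovered 92 of 98 genes planted at 2-fold and 99 of 99 at 4-fold among 11381 genes run, and called 15 unchanged genes. edgeR recovered 91 of 100 and 100 of 100 among 11428 genes run, with 16 unchanged genes called. For DI150 against PBS, limma recovered 93 of 98 and 99 of 99 among 11381 genes, with 25 unchanged genes called, and edgeR 93 of 100 and 99 of 100 among 11428 genes, with 26. A planted list was called by camera in the I80 simulation, and 0 of 30 unchanged lists were. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes that share reads with close relatives, named as such where they appear, are uncertain because the treatment of shared reads is not given in the sources used here.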

Results

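MTflEcad cells are epithelial cells from a mammary tumour of an MMTV-Neu mouse, a strain in which a Neu (ERBB2) oncogene is expressed in the mammary gland. Cells were given H2O2 every day for 7 months at 80 µM, which gave the line I80, or at 150 µM, which gave the line DI150, and untreated cells, here PBS, served as the control. RNA was sequenced in 2 libraries per line. Each dose is represented by 1 line, so dose and line cannot be separated. The libraries held 26608715 and 24729527 assigned reads in PBS, 25629579 and 24260895 in I80, and 21017849 and 26205388 in DI150, and 13905 to 15015 genes had at least 1 read. A single read was worth 0.0376 to 0.0476 CPM.

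The log2 values of replicate libraries correlated across genes at r = 0.991 in PBS, 0.998 in I80 and 0.997 in DI150. PBS and treated libraries correlated at 0.804 to 0.827, and I80 and DI150 libraries at 0.959 to 0.961 (genes are not independent replicates). The first principal component separated PBS from both treated lines and held 82.7% of the variance, and the next separated I80 from DI150 with 14.5%. Replicates differed by more than counting noise in each group, with a chi-square per degree of freedom of 24.4 in PBS, 4.54 in I80 and 9.82 in DI150. The plot of named genes across the libraries shows the levels behind several of the changes described here.

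**Figure D1:**
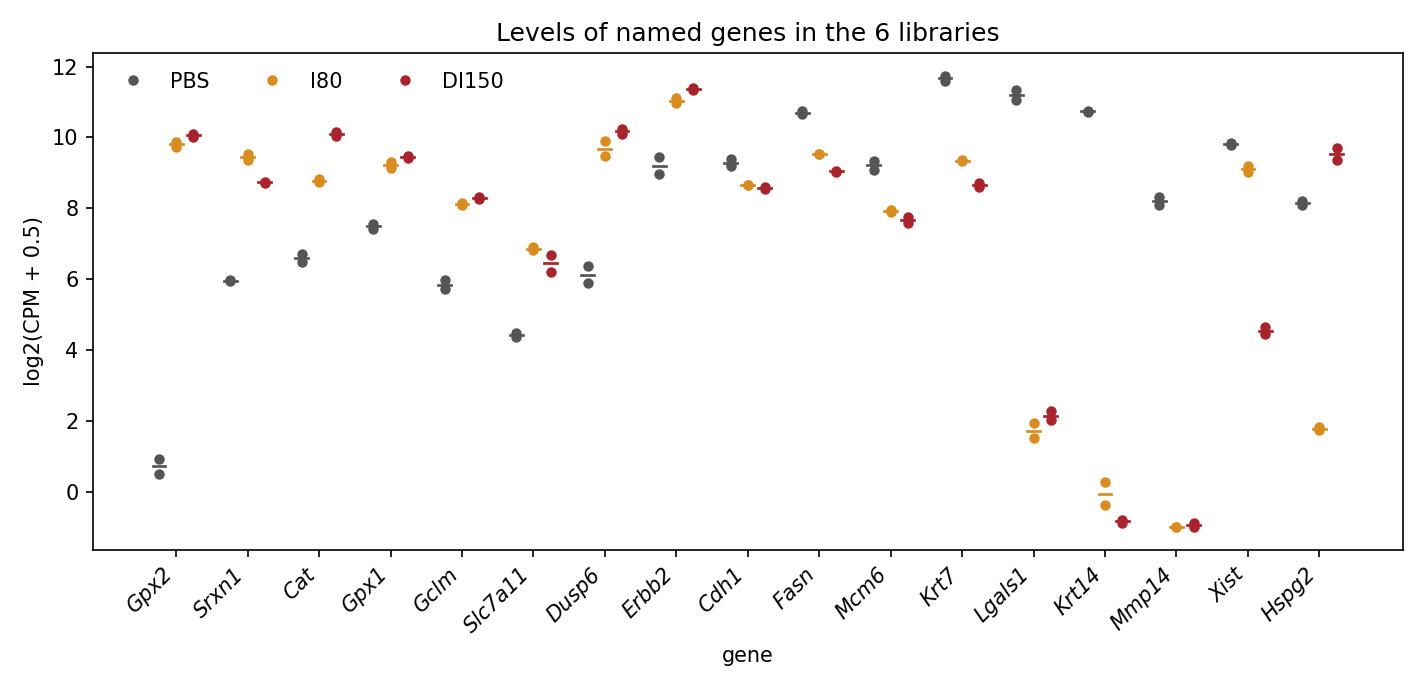
Levels of 17 named genes on the log2(CPM + 0.5) scale. Each point is 1 library and each bar the mean of the 2 libraries of PBS (grey), I80 (orange) or DI150 (red). Gpx2 stands at 1.16 CPM in PBS and at 894.8 and 1065 CPM in I80 and DI150, while Krt14 goes from 1701 CPM to under 1 CPM.

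I80 against PBS asks which transcripts differed after 7 months of 80 µM H2O2. Gpx2, a glutathione peroxidase that reduces H2O2, rose from 1.16 ± 0.326 CPM in PBS to 894.8 ± 55.5 CPM in I80 (SD, n = 2 each), a 771.2-fold difference (log2 fold change 9.09 ± 0.12 SE, limma adjusted p = 2.68e-08). Krt14, a keratin of basal mammary epithelium, fell from 1701 ± 38.1 to 0.487 ± 0.302 CPM, 3493-fold lower (limma adjusted p = 3.47e-08). Mmp14, a membrane-bound matrix metalloproteinase, stood at 294.1 ± 34.1 CPM in PBS and had no read in I80, at least 2443-fold lower. Most tested members of the NRF2 and peroxide removal lists rose and most of the mesenchymal and Wnt lists fell, calls that camera made with its preset correlation and not with an estimated one (adjusted p = 0.714 to 0.799). Gpx2 (gene 14776) lies on chromosome 12 of GRCm38 at 76792335 to 76795554, Krt14 (gene 16664) on chromosome 11 at 100203162 to 100207510, and Mmp14 (gene 17387) on chromosome 14 at 54431598 to 54442456.

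In all, 3687 genes were higher and 3904 lower in I80 than in PBS, 66.4% of the 11428 tested. Of these, 1052 were at least 2-fold higher and 1342 at least 2-fold lower, and 67 and 232 passed 16-fold. The PBS and I80 libraries did not overlap for 83.7% of the tested genes, against the 33.3% that chance gives with 2 libraries per group. Besides Gpx2, large rises were those of Col27a1, a collagen, from 0.800 to 598.9 CPM, Olfml3 from 0.659 to 277.6 CPM, the carbonyl reductase Cbr3 from 0.494 to 196.1 CPM, and Gsta3 from 0.789 to 247.2 CPM (limma adjusted p from 6.28e-09 to 7.11e-08). Gsta3 is 1 of several similar glutathione S-transferase genes and its count is uncertain. The largest falls besides Krt14 and Mmp14 were those of Lgals1, a galectin, from 2353 to 2.84 CPM, the collagen chaperone Serpinh1, Col8a1 and Dynap. Serpinh1 and Col8a1 had 2 reads each in I80, giving PBS to I80 ratios of 6768 (95% interval 1873 to 55892) and 6607 (1829 to 54564), and Dynap was 1489-fold lower.

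Of 37 tested targets of NRF2, the transcription factor of the response to oxidants and electrophiles, 28 rose, 4 fell and 5 did not pass (camera adjusted p = 1.57e-06, and adjusted p = 0.799 with an estimated correlation). Akr1b8, an aldo-keto reductase, went against the list, from 76.0 ± 0.628 CPM to 0 reads in I80, at least 631.3-fold lower. Of 29 tested genes that remove H2O2 and superoxide, 17 rose and 4 fell (camera adjusted p = 0.0104, and adjusted p = 0.714 with an estimated correlation). Catalase (Cat) rose from 96.7 ± 10.7 to 440.0 ± 22.1 CPM, 4.55-fold (limma adjusted p = 7.47e-07). Gpx1 rose from 179.4 ± 14.03 to 601 ± 49.0 CPM, the sulfiredoxin Srxn1 from 61.8 ± 1.46 to 696.5 ± 54.4 CPM, and the methionine sulfoxide reductase Msrb2 from 3.87 ± 1.16 to 27.7 ± 0.962 CPM, while Mgst3 fell from 53.4 ± 4.04 to 5.19 ± 0.00299 CPM. The glutathione pathway genes Slc7a11, which carries cystine into the cell, and Gclm, a subunit of the first enzyme of glutathione synthesis, rose 5.51-fold and 4.83-fold. Not every familiar NRF2 target moved this way. Hmox1 fell from 23.3 ± 5.42 to 15.5 ± 2.78 CPM (limma adjusted p = 0.0242), a call lost without I80 replicate 1 (adjusted p = 0.168) or PBS replicate 2 (0.149), and Nqo1 stood at 0.863 ± 0.21 and 1.09 ± 0.439 CPM (limma adjusted p = 0.498, and 0.0259 under quantile normalization).

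Of 19 tested genes of the mesenchymal list, 15 fell and 2 rose (camera adjusted p = 0.000217, and adjusted p = 0.714 with an estimated correlation). S100a4 fell from 612.4 ± 7.38 to 6.49 ± 1.07 CPM, and Col1a2 went from 15.3 ± 0.0213 CPM to 0 reads, at least 127.2-fold lower. Vim was at 18.8 ± 1.61 and 15.7 ± 0.78 CPM (limma adjusted p = 0.1). Zeb1 was too low to test, at 0.752 and 0.728 CPM in PBS and at 0 and 0.041 CPM in I80. Of 27 tested matrix genes 16 fell and 8 rose (camera adjusted p = 0.0259, and adjusted p = 0.818 with an estimated correlation). Col4a6, a basement membrane collagen, fell from 154.4 ± 17.2 to 0.164 ± 0.176 CPM, and the proteoglycans Vcan and Hspg2 fell 156.4-fold and 95.6-fold. Of 15 tested basal and myoepithelial genes 10 fell and 2 rose (camera adjusted p = 0.0286, and adjusted p = 0.818 with an estimated correlation), with Krt15 falling from 33.0 ± 5.26 to 0.0997 ± 0.0245 CPM and Id4 from 38.2 ± 15.5 to 1.05 ± 0.211 CPM. Of 13 tested Wnt genes 9 fell and 3 rose (camera adjusted p = 0.0308, and adjusted p = 0.714 with an estimated correlation). The Wnt ligand Wnt10a fell from 159.8 ± 10.0 to 1.04 ± 0.073 CPM, while Wnt7a and Notum, which encodes an enzyme that inactivates Wnt proteins, had no read in I80 and were at least 273.5-fold and 617.1-fold lower. Beside these falls, the summed fibroblast markers stood at 23.6 and 26.2 CPM in PBS and at 26.2 and 27.3 CPM in I80. That sum held opposite moves, since Col1a2 fell as given above and Pdgfra rose. Pdgfra stood at 5.04 and 5.50 CPM in PBS and at 14.5 and 15.1 CPM in I80. Csf1r, a gene of macrophages, was at 7.67 and 14.5 CPM in PBS and at 0 in I80. Without PBS replicate 2 the matrix and basal lists were no longer called (camera adjusted p = 0.0611 and 0.0598).

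Of 32 tested genes of cholesterol and fatty acid synthesis, 25 fell and 4 rose (camera adjusted p = 0.00216, and adjusted p = 0.818 with an estimated correlation). The sterol enzymes Fdft1, Msmo1 and Hsd17b7 fell 3.49-fold, 3.44-fold and 2.38-fold, and Tm7sf2, a sterol reductase, rose from 9.03 ± 4.21 to 29.8 ± 0.802 CPM. Erbb2, the mouse gene of the receptor that the transgene carries, rose from 596.8 ± 137 to 2095 ± 149 CPM (log2 fold change 1.83 ± 0.15 SE, limma adjusted p = 2.42e-05), and reads of a rat Neu transgene cannot be told apart from it in this table. Dusp6, a phosphatase induced by MAPK signalling, rose from 70.5 ± 16.2 to 830.6 ± 173 CPM. The E-cadherin gene Cdh1 fell from 623.8 ± 63.2 to 402.5 ± 3.17 CPM (limma adjusted p = 0.000305), and Epcam stood at 605.9 ± 32.1 and 681.7 ± 48.3 CPM (0.122). The log2 fold change of Cdh1 was -0.628, near the median of -0.636 over the 620 tested genes of its chromosome 8. Cdkn1a, the p21 inhibitor of the cell cycle, rose from 162.3 ± 70.2 to 311.9 ± 38.9 CPM (limma adjusted p = 0.00982), with an adjusted p of 0.0643 without I80 replicate 1. The proliferation marker Mki67 stood at 864.5 ± 22.9 and 1121 ± 86.8 CPM (limma adjusted p = 0.0519). Apart from fits with a library left out, it passed with edgeR (adjusted p = 0.0341), DESeq2 (0.00953), median-of-ratios scaling (0.0398), quantile normalization (0.038) and robust variances (0.0464). It also passed in limma fits on the 4 libraries compared (adjusted p = 0.00954), with the replicate block (0.0174) and with DI150 replicate 3 as the second sample of that block (0.0249). Camera thus called 7 lists, none of which it called with an estimated correlation (lowest adjusted p = 0.714, and 0 lists at an unadjusted p under 0.05), while fry called 23. Counts adjusted over the list alone were the same for these 7 lists except cholesterol synthesis, where 5 rose and 26 fell.

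**Figure D2:**
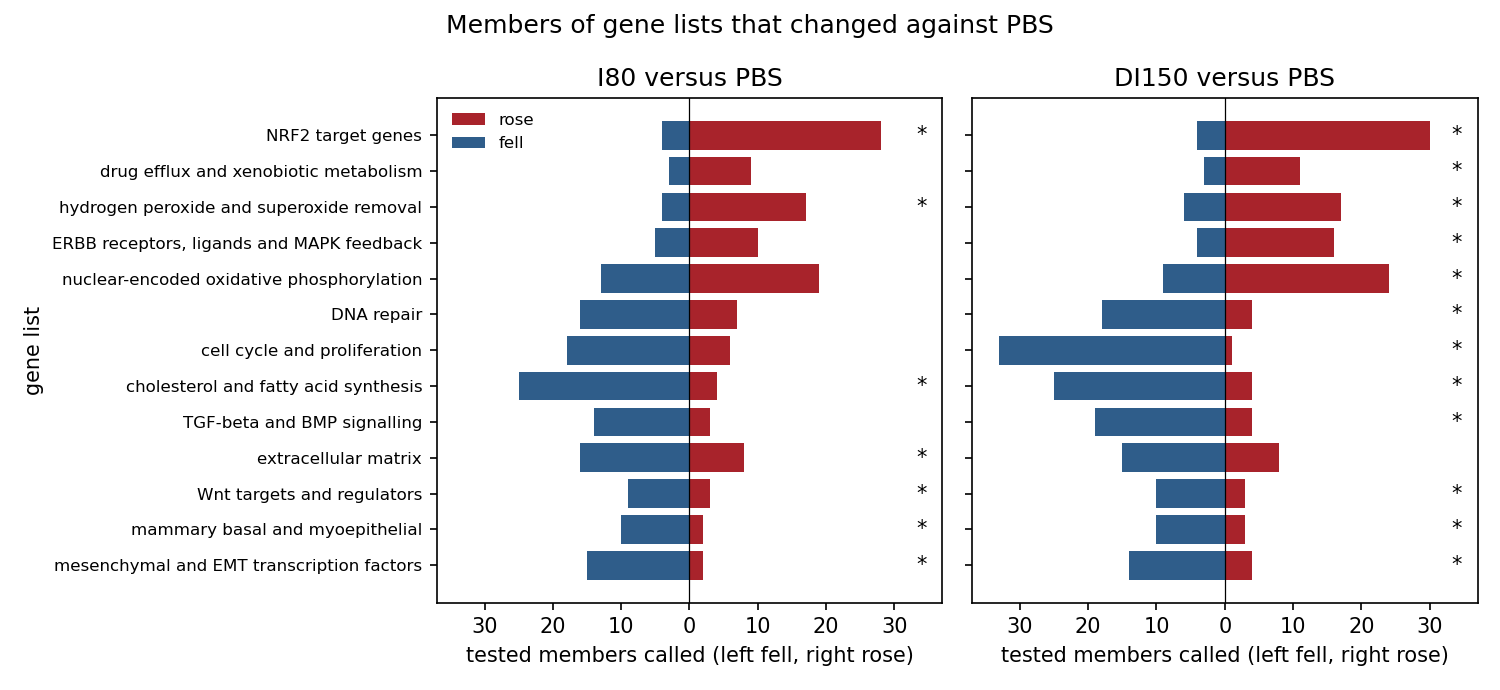
Numbers of tested members that rose (red, right) and fell (blue, left) against PBS, for the 13 gene lists called in either comparison. A star marks a list called by camera with its preset correlation, and with an estimated correlation none was called. In both lines most NRF2 targets rose (28 and 30 of 37) and most cholesterol and fatty acid genes fell (25 of 32 in each).

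DI150 against PBS asks the same at 150 µM. Gpx2 again rose, from 1.16 ± 0.326 to 1065 ± 36.1 CPM (918-fold, limma adjusted p = 1.32e-08). Catalase rose 11.3-fold, from 96.7 ± 10.7 to 1098 ± 54.0 CPM (SD, n = 2 each; log2 fold change 3.50 ± 0.09 SE, limma adjusted p = 7.54e-08). The channel gene Pkd2l1 rose from 0.139 ± 0.0898 to 371.6 ± 50.7 CPM, and Xist, the noncoding RNA that silences an X chromosome, fell from 900.7 ± 23.3 to 22.9 ± 2.07 CPM. Most tested members of the NRF2 and peroxide removal lists rose, and most of the cell cycle, basal, mesenchymal, Wnt, TGF-beta and cholesterol lists fell, calls that camera made with its preset correlation and not with an estimated one (adjusted p = 0.750 for each). Cat (gene 12359) lies on chromosome 2 of GRCm38 at 103453904 to 103485153, Pkd2l1 (gene 329064) on chromosome 19 at 44147637 to 44248328 and Xist (gene 213742) on the X chromosome at 103460373 to 103483233. Since the use of strand in counting is not given, Xist reads cannot be told apart from those of its antisense partner Tsix.

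In DI150, 3733 genes were higher and 4120 lower than in PBS, 68.7% of those tested, with 1167 and 1299 past 2-fold and 82 and 243 past 16-fold. Libraries did not overlap for 83.5% of genes, against 33.3% by chance. Large rises were also those of Col27a1 (to 449.2 CPM), the transcription factor Hlf (from 0.923 to 353.5 CPM), Gsta3 (to 298.1 CPM, with the same uncertainty) and Cbr3 (to 155 CPM). Krt14 had 3 reads left in DI150, a PBS to DI150 ratio of 26784 (95% interval 9165 to 129882). Tns4, which encodes a protein of focal adhesions, had 2 (ratio 15230, interval 4216 to 125767), and Mmp14 and Col8a1 had 1 each (ratios 13845, interval 2484 to 546868, and 12508, interval 2245 to 494078). Dynap had none and was at least 2523-fold lower, and Lgals1 fell to 3.96 ± 0.553 CPM, 594.4-fold lower.

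Of the NRF2 targets 30 rose, 4 fell and 3 did not pass (camera adjusted p = 5.88e-07, and adjusted p = 0.750 with an estimated correlation). Nqo1 was among those that rose, from 0.863 ± 0.21 to 3.79 ± 0.829 CPM (limma adjusted p = 0.000722), while Hmox1 fell from 23.3 ± 5.42 to 12.97 ± 0.159 CPM (0.00497) and Akr1b8 had no read, at least 590.8-fold lower than in PBS. Of the peroxide removal genes 17 rose and 6 fell (camera adjusted p = 0.0123, and adjusted p = 0.750 with an estimated correlation). Gpx1 rose to 701.1 ± 15.5 CPM, 3.91-fold, Srxn1 to 423.5 ± 7.58 CPM, 6.86-fold, and Slc7a11 to 87.7 ± 20.3 CPM, 4.19-fold. Of 15 tested genes of drug efflux and xenobiotic metabolism 11 rose and 3 fell (camera adjusted p = 0.014, and adjusted p = 0.750 with an estimated correlation), a call lost with no expression filter (adjusted p = 0.154). Gstm1 and Gstm2, glutathione S-transferases whose shared reads make both uncertain, rose 65.8-fold and 48.9-fold, and the transporter gene Abcc5 fell 50.8-fold.

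Of 41 tested cell cycle genes 33 fell and 1 rose (camera adjusted p = 0.000198, and adjusted p = 0.750 with an estimated correlation). Mcm6, a subunit of the replicative helicase, fell from 596 ± 74.9 to 205.1 ± 16.7 CPM, Mcm5 from 616.5 ± 92.1 to 286.2 ± 4.53 CPM, and the transcription factor E2f1 from 56.5 ± 2.82 to 27.5 ± 0.615 CPM. Mki67 was at 864.5 ± 22.9 and 815.9 ± 187 CPM (limma adjusted p = 0.551, and 0.0304 without DI150 replicate 3). Of 30 tested DNA repair genes 18 fell and 4 rose (camera adjusted p = 0.0338, and adjusted p = 0.750 with an estimated correlation). The base excision genes Neil3 and Apex1 fell 2.50-fold and 1.97-fold. The repair list was not called from DESeq2's values (adjusted p = 0.117) or without PBS replicate 1 (0.0903). Of 45 tested nuclear genes of oxidative phosphorylation 24 rose and 9 fell (camera adjusted p = 0.0246, and adjusted p = 0.750 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.0672). Atp5pb, a subunit of ATP synthase, rose from 175.5 ± 10.8 to 416.4 ± 8.26 CPM, and the cytochrome oxidase subunit Cox5a from 145.5 ± 5.99 to 277.6 ± 19.6 CPM.

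Mesenchymal genes fell in 14 of 19 cases and rose in 4 (camera adjusted p = 0.00255, and adjusted p = 0.750 with an estimated correlation). Sparc, a secreted matrix glycoprotein, fell from 170.9 ± 1.35 to 0.286 ± 0.134 CPM and Vim from 18.8 ± 1.61 to 11.9 ± 1.13 CPM, and the untested Zeb1 was at 0.333 and 0.076 CPM. Of the basal genes 10 fell and 3 rose (camera adjusted p = 0.00941, and adjusted p = 0.750 with an estimated correlation), with Id4 at 1.90 ± 0.125 CPM against 38.2 ± 15.5 in PBS. All 13 tested Wnt genes passed, 10 lower and 3 higher (camera adjusted p = 0.00979, and adjusted p = 0.750 with an estimated correlation), and Wnt4 fell from 24.7 ± 2.85 to 0.362 ± 0.0263 CPM. Of 24 tested genes of TGF-beta and BMP signalling 19 fell and 4 rose (camera adjusted p = 0.00315, and adjusted p = 0.750 with an estimated correlation). Inhba, a subunit of activin, fell from 24.3 ± 3.74 to 0.596 ± 0.237 CPM and its antagonist Fst from 50.8 ± 9.24 to 6.95 ± 0.208 CPM, while the co-receptor Tgfbr3 rose from 0.269 ± 0.151 to 13.97 ± 2.32 CPM. Beside these lists, fibroblast markers summed to 27.2 and 28.8 CPM in DI150, a sum that can hide opposite moves of its members. Pdgfra made up 19.0 and 18.4 CPM of it, against 5.04 and 5.50 CPM in PBS. Csf1r was at 0 in DI150. Lpl, the lipoprotein lipase gene and the only tested member of the adipocyte list, rose from 0 reads in PBS to 12.7 ± 1.32 CPM, at least 108.4-fold higher.

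Cholesterol and fatty acid genes fell in 25 of 32 cases and rose in 4 (camera adjusted p = 0.00184, and adjusted p = 0.750 with an estimated correlation), with the fatty acid synthase gene Fasn falling from 1658 ± 79.3 to 528.3 ± 8.14 CPM. Of 23 tested genes of ERBB receptors, their ligands and MAPK feedback 16 rose and 4 fell (camera adjusted p = 0.0123, and adjusted p = 0.750 with an estimated correlation). Erbb2 (gene 13866, chromosome 11 of GRCm38 at 98412484 to 98437716) rose from 596.8 ± 137 to 2642 ± 78.1 CPM (limma adjusted p = 9.01e-06), again with transgene reads not told apart. The feedback genes Dusp6 and Spry4 rose 16.3-fold and 17.0-fold, and Egfr fell from 28.8 ± 4.63 to 2.46 ± 0.292 CPM. Cdh1 (gene 12550, chromosome 8 at 106603350 to 106670247) fell to 381.1 ± 10.3 CPM (limma adjusted p = 0.000153), Epcam rose to 1055 ± 75.4 CPM (0.000115), and Cdkn1a rose to 336.1 ± 41.2 CPM (0.00589). The 620 tested genes of chromosome 8 had a median log2 fold change of -0.564 in this comparison, and Cdh1 had -0.707. Camera called 12 lists, none of them with an estimated correlation (lowest adjusted p = 0.750, and 1 list at an unadjusted p under 0.05), and fry called 28. Adjusted over the list alone the counts were the same for these 12 lists, except that 11 basal genes fell.

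The treated lines shared much of their difference from PBS. Both had lost Krt14, Mmp14, Lgals1, Col8a1 and Dynap from the abundant transcripts, and both had gained Gpx2, Col27a1, Cbr3 and Gsta3. In all, 2690 genes were higher in both lines and 3038 lower in both, 95.1% of the genes called in both comparisons. A further 294 genes were called in opposite directions, while 1569 were called in I80 alone and 1831 in DI150 alone. Independent lists of these sizes (n1 × n2 / N) would share 1204.4 higher and 1407.5 lower genes. Simulated unchanged groups, compared with shared simulated PBS libraries, shared a mean of 0.06 genes, and at most 1, in 100 simulations. The simulations gave the 3 groups the same spread, whereas in the data PBS replicates differed most (chi-square per degree of freedom 24.4). The simulated values may thus understate what shared PBS libraries alone give. The log2 fold changes correlated across genes at r = 0.889, against a mean of 0.5 in the simulations, with a covariance of 1.57 against 0.0095 simulated, a difference of 1.56 (genes are not independent replicates). A split of the 2 PBS libraries would leave 1 for each comparison, so they were not divided, and part of the excess of shared calls may come from the shared controls. A set of 68 genes stood at 20 CPM or more in both PBS libraries and under 0.5 CPM in all 4 treated libraries, Serpinh1, Akr1b8, Notum, Wnt7a and Col4a6 among them. The reverse held for 6 genes, Prkaa2, Adcy8, Col15a1, Masp1, Otos and 3830417A13Rik, and these 6 were chosen for naming after their values were seen.

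**Figure D3:**
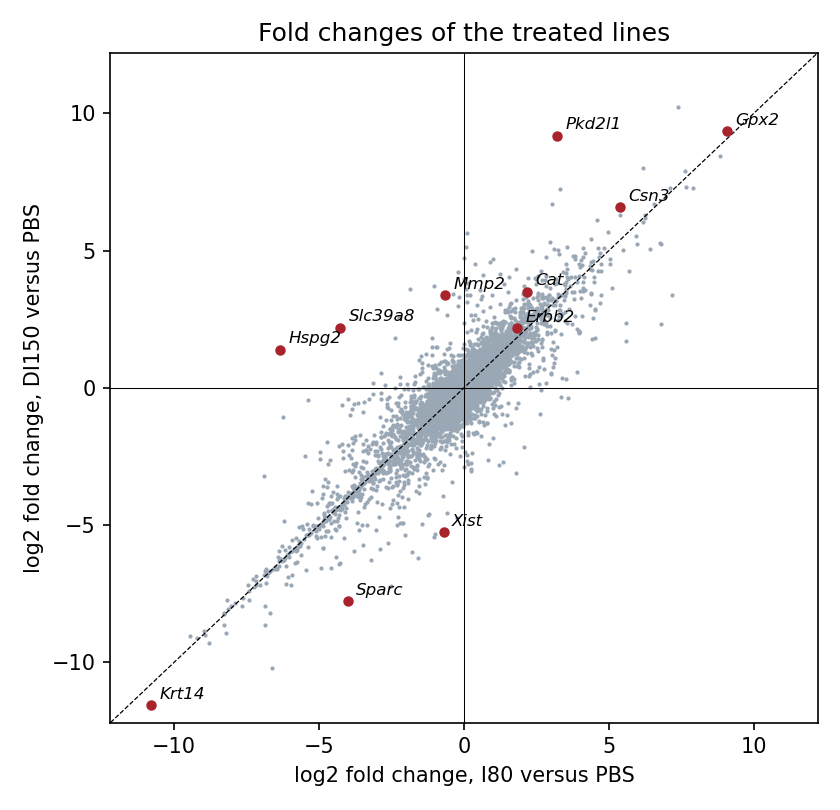
Log2 fold change against PBS of the 11428 tested genes in I80 (horizontal) and DI150 (vertical), with the line of equal change dashed. The changes correlate at r = 0.889, and Pkd2l1, Mmp2, Hspg2, Slc39a8, Xist and Sparc are labelled away from the dashed line.

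DI150 against I80 asks where the treated lines differ, which is also the test of whether their effects against PBS differ. Hspg2, the perlecan proteoglycan of basement membranes, stood at 2.95 ± 0.143 CPM in I80 and 745.1 ± 124 CPM in DI150 (252.6-fold, log2 fold change 7.75 ± 0.11 SE, limma adjusted p = 1.01e-07). The metal transporter gene Slc39a8 stood at 0.140 ± 0.0229 and 55.9 ± 6.02 CPM, Pkd2l1 at 5.35 ± 0.218 and 371.6 ± 50.7 CPM, and Sema3d, a secreted guidance protein, at 0.124 ± 0.175 and 26.0 ± 0.269 CPM (n = 2 each). The sodium channel gene Scn10a had 2 reads in I80 and 24.1 ± 0.246 CPM in DI150, a ratio of 601.7 (95% interval 166.2 to 4974). Lower in DI150 were Xist, from 553.1 ± 41.8 to 22.9 ± 2.07 CPM (limma adjusted p = 3.12e-07), the tubulin gene Tubb2b, the phosphatase gene Acp5 and the kinase gene Hunk, by 24.1-fold, 81.2-fold, 36.0-fold and 25.7-fold in turn. Smpd1, a sphingomyelinase, went from 11.8 ± 0.136 CPM to 0 reads, at least 92.1-fold lower. Hspg2 (gene 15530) lies on chromosome 4 of GRCm38 at 137468751 to 137570630 and Slc39a8 (gene 67547) on chromosome 3 at 135816882 to 135888572.

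In this comparison 2503 genes were higher and 2505 lower in DI150, 43.8% of those tested, with 389 and 354 past 2-fold, and libraries did not overlap for 78.5% of genes against 33.3% by chance. Of the cell cycle genes 20 fell and 2 rose from I80 to DI150 (camera adjusted p = 0.00237, and adjusted p = 0.948 with an estimated correlation). E2f1 fell from 58.5 ± 1.39 to 27.5 ± 0.615 CPM, Cdc20, an activator of mitotic exit, from 239.2 ± 10.4 to 141.5 ± 8.71 CPM and the checkpoint kinase gene Ttk from 46.1 ± 0.996 to 27.2 ± 2.43 CPM, while E2f2 rose from 13.1 ± 0.0551 to 20.6 ± 1.4 CPM. Of the ERBB and MAPK feedback genes 9 rose and 1 fell (camera adjusted p = 0.043, and adjusted p = 0.948 with an estimated correlation). Spry4 rose 2.84-fold and the ligand gene Nrg1 from 7.39 ± 0.479 to 15.2 ± 0.816 CPM, and Egfr fell 4.71-fold. The ERBB list was no longer called with a filter at 5 CPM (adjusted p = 0.0589), without DI150 replicate 1 (0.169) or without I80 replicate 2 (0.135). No list was called with an estimated correlation (lowest adjusted p = 0.948, and 0 lists at an unadjusted p under 0.05), and the lists that fry called were 2 others, oxidative phosphorylation and noncoding RNAs. Counts adjusted over the list alone were the same for the called lists.

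Among genes of single interest, catalase was 2.50-fold higher in DI150 than in I80 (log2 fold change 1.32 ± 0.09 SE, limma adjusted p = 6.25e-05) and Nqo1 3.48-fold higher (0.00345). The NRF2 list as a whole was divided between the treated lines, with 8 genes higher and 9 lower in DI150 (camera adjusted p = 0.846). Of its members, G6pdx, which supplies NADPH, fell from 708.4 ± 3.22 to 371.8 ± 23.5 CPM and the ferritin gene Fth1 rose from 1170 ± 6.0 to 2136 ± 325 CPM. The log2 fold change of the X-linked G6pdx was -0.93, where the tested genes of the X chromosome had a median of -0.59. Mmp2, a secreted matrix metalloproteinase, rose from 1.78 ± 0.129 to 36.5 ± 5.92 CPM and Twist1 from 6.17 ± 0.328 to 19.0 ± 0.74 CPM, whereas Sparc fell from 10.1 ± 0.703 to 0.286 ± 0.134 CPM and fibronectin (Fn1) from 285.8 ± 29.5 to 102.8 ± 9.8 CPM. Epcam was higher in DI150 (limma adjusted p = 0.00126), while Cdh1 (0.467), Gpx1 (0.0657, and 0.0325 with DESeq2), Cdkn1a (0.768) and Hmox1 (0.327) did not pass. Erbb2 differed with a limma adjusted p of 0.102, and passed with DESeq2 (0.0298), in a fit on the 4 libraries compared (0.0322) and without PBS replicate 1 (0.0239) or 2 (0.0224). Slc7a11 differed with 0.0524, and passed with DESeq2 (0.0424), robust variances (0.046) and without DI150 replicate 1 (0.0104). Mki67 was lower in DI150 (limma adjusted p = 0.032), a call lost without PBS replicate 1 (adjusted p = 0.0758) or 2 (0.0755), I80 replicate 1 (0.0837) or 2 (0.183) or DI150 replicate 1 (0.136), with no filter (0.0723), without a trend (0.0624) and in a fit on the 4 libraries compared (0.0746). Vim was lower (0.0337), a call lost without any 1 of the 4 treated libraries (0.0589 to 0.192), with no filter (0.0587) and with DESeq2 (0.0574). Leaving out a treated library lowered the counts of higher and lower genes to 1295 and 1246 (without I80 replicate 1), 1300 and 1187 (I80 replicate 2), 1561 and 1451 (DI150 replicate 1), and 1547 and 1662 (DI150 replicate 3).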

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

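The test between the treated lines, used here, was planned, and the 3 genes named were chosen by their size after the result was seen. A difference between groups drew attention to 294 genes, which were called in opposite directions in I80 and DI150, each against PBS. All of them were called between the lines too. That call was bound to follow and adds no support, since the change between the lines is the difference of the 2 changes against PBS. Of the 294 genes, 20 were past 2-fold in each direction. Hspg2 was lower in I80 than in PBS (log2 fold change -6.36) and higher in DI150 (1.39), and the direct test of DI150 against I80 gave 7.75 (limma adjusted p = 1.01e-07). Slc39a8 was lower in I80 and higher in DI150 likewise, with 6.46 between the lines (8.7e-07). Sema3d followed the same course, with 5.44 between the lines (6.77e-06). Each line is 1 dose, so a difference of dose and a difference of line are confounded here, and no explanation was tested for these genes.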

How the results depend on the processing

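The replicate block in which DI150 replicate 3 stands for the second DI150 sample was chosen after seeing the data, and the other alternatives were planned. Over 20 settings, 7745 of 8037 comparisons of named genes kept direction and side of the threshold, 263 were weaker, 20 stronger, 9 moved and 0 reversed. Of 1830 list comparisons 1687 stayed the same, 32 were weaker, 83 stronger, 27 moved and 1 reversed, and of 252 counts 225 stayed within 1.5 times the main count. Asking for an absolute log2 fold change of at least 1 left 1052 higher and 1342 lower genes in I80 against PBS, 1167 and 1299 in DI150 against PBS, 389 and 354 between the lines, and 1781 called the same way in both lines, fewer by construction. With a filter at 5 CPM, 1 list was called between the lines. From DESeq2's values 15 lists were called in I80 against PBS and 5 between the lines. Camera with an estimated correlation called 0 lists in I80 against PBS, 0 in DI150 against PBS and 0 in DI150 against I80, and fry called 23 and 28 lists against PBS. The list of iron handling reversed under fry in DI150 against PBS, with a median log2 fold change of -0.08 (-0.084, fry adjusted p = 0.0319), where camera pointed up (camera adjusted p = 0.953). For these changes of lists the cause was not tested. Simulated unchanged groups shared a mean of 0.06 genes, low by construction. Without 1 library at a time, counts between the lines ran from 1295 to 3008 higher and from 1187 to 2965 lower. Lists called ran from 1 to 4. These fits assume that a lone sample varies like the other groups. Gene counts were lowest without an I80 library and highest without a PBS library. A smaller number of libraries alone cannot explain the rise. The fit on the 4 libraries compared, with no PBS library, gave 3005 higher and 2960 lower, against 2503 and 2505 in the main fit. The main fit pools the spread of the 3 groups, and PBS replicates differed most (chi-square per degree of freedom 24.4). Whether that spread lowered the main counts was not tested, nor were other causes. Without 1 library at a time, the overlap ran from 4712 to 5845 genes. With the replicate number as a block, 3471 genes were higher and 3704 lower in I80 against PBS and the TGF-beta list was called (0.0422), and with DI150 replicate 3 as the second sample 3679 and 3881, although libraries that share a number share only a number (r = 0.023 between paired deviations). At 1 read per 0.0376 to 0.0476 CPM, depth limits folds for genes near 0 to lower bounds.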

Other observations

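The tests chosen only after the result was seen are the shuffles of gene positions, the count of markers of other cell types, the bound on treated-like cells and the comparison of whole profiles, while the others were written before it. The lists that camera did not call in the main test are given first. In I80 against PBS these were TGF-beta and BMP signalling (3 rose, 14 fell, camera adjusted p = 0.0575, and 0.0238 without PBS replicate 1 or 0.0392 without I80 replicate 1), MHC class I presentation (2 and 9, 0.0859, and 0.0213 without PBS replicate 1), epithelial junctions (7 and 20, 0.0859, and 0.0213 without PBS replicate 1) and immediate early genes (3 and 11, 0.0898, and 0.0438 without I80 replicate 1). Ribosomal proteins (18 and 7, 0.0955), drug efflux (9 and 3, 0.148), the cell cycle (6 and 18, 0.148), NF-kB targets (6 and 12, 0.148), YAP targets (4 and 10, 0.148) and ERBB signalling (10 and 5, 0.225) did not pass either in that test. Targets of p53 stood at 14 and 5 (0.17, and 0.024 without PBS replicate 2), glutathione synthesis at 6 and 4 (0.225), DNA repair at 7 and 16 (0.261), axon guidance at 4 and 6 (0.27), luminal genes at 4 and 8 (0.272), oxidative phosphorylation at 19 and 13 (0.351) and the interferon response at 4 and 11 (0.375). Glycolysis and hypoxia (11 and 9), heat shock (3 and 9) and noncoding RNAs (1 and 3) had an adjusted p of 0.422 each, the integrated stress response (9 and 9) 0.611, iron handling (8 and 8) 0.824 and ER chaperones (7 and 7) 0.865. From DESeq2's values, camera called TGF-beta signalling (0.0147), NF-kB targets (0.015), MHC class I presentation (0.0194), ERBB signalling (0.0261), and epithelial junctions, drug efflux, luminal genes and glycolysis (0.0343 each). TGF-beta signalling was also called with no filter (0.00867), quantile normalization (0.0325) and edgeR (0.0416), epithelial junctions with no filter (0.034) and quantile normalization (0.0427), and axon guidance with no filter (0.0462).

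In DI150 against PBS the uncalled lists nearest the threshold were extracellular matrix (8 rose, 15 fell, camera adjusted p = 0.0632, 0.0299 without DI150 replicate 1 and 0.0497 without I80 replicate 1 or 2), epithelial junctions (8 and 21, 0.0654, 0.0175 without PBS replicate 1 and 0.0299 without DI150 replicate 1) and glycolysis and hypoxia (18 and 9, 0.0921). Targets of p53 (11 and 6, 0.383) and heat shock (1 and 6, 0.27) were called without PBS replicate 2, with 0.0434 each. Extracellular matrix was also called with no filter (0.0223), a filter at 5 CPM (0.0256), quantile normalization (0.0294), median-of-ratios scaling (0.05 after rounding), the 4 libraries compared (0.0497) and DESeq2 (0.000493). Epithelial junctions were called with no filter (0.0223), quantile normalization (0.0294) and DESeq2 (0.0148), glycolysis with a filter at 5 CPM (0.00538) and DESeq2 (0.00393), and noncoding RNAs (1 and 2, 0.6) with DESeq2 (0.00598). Between the treated lines they were drug efflux (9 and 2, 0.0687, 0.014 without DI150 replicate 3 and 0.0447 without I80 replicate 1) and immediate early genes (7 and 1, 0.0897, 0.0179 without DI150 replicate 3 and 0.0379 without I80 replicate 1). The integrated stress response (3 and 5, 0.411) was called without DI150 replicate 1, with 0.00786. Drug efflux was also called with quantile normalization (0.0498), edgeR (0.0428) and DESeq2 (0.00209), and DESeq2's values also gave calls of noncoding RNAs (1 and 1, 0.871 in the main test, 0.000807) and basal genes (1 and 7, 0.289, 0.0164). Production of peroxide, fibroblast, immune, endothelial, adipocyte and mitochondrially encoded genes had too few tested members, with 4, 4, 2, 2, 1 and 0. Endothelial markers summed to 3.01 to 8.74 CPM over the libraries, and immune markers to 9.92 and 17.6 CPM in PBS and 2.62 to 4.53 CPM in the treated libraries.

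Genes of the same chromosome tended to shift together. Camera called 9 chromosomes in I80 against PBS, 15 in DI150 against PBS and 14 between the lines, and 0 with an estimated correlation (lowest adjusted p = 0.105, with 18 at an unadjusted p under 0.05), the median log2 fold change of chromosome 8 being -0.64 in I80 and that of X -0.59 in DI150 against I80. The spread of chromosome medians was at least 5.298 times the highest of 1000 shuffles. After regression on GC content, transcript length and expression level it was at least 5.196 times. These values argue against random placement and those properties. Among genes changed less than 2-fold it was at least 4.649 times. That value cannot decide on a few strongly changed neighbours, since a few genes hardly move the median of a chromosome. Copy number differences cannot be told apart from other shifts of whole chromosomes, and no DNA was measured. Any shift of a whole chromosome would keep its sign in both parts and both expression classes, as 33 of 38 calls did (86.8%). The others changed sign between the parts, such as chromosome 10 in DI150 against PBS, with medians of -0.209 and 0.397. Those were not shifted as a whole, and changes of parts of chromosomes were not tested. Exposure to H2O2 stays open and untested, confounded with line.

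A set of 68 genes was abundant in PBS and near 0 in both treated lines. Fibroblasts, leukocytes, endothelial cells or adipocytes in the PBS cultures met the bound written first. Csf1r reached up to 32.3% of the median PBS level of the lost genes, and Pdgfra, which met the bound too, was higher in all treated libraries. Such cells bring all their abundant transcripts. Of the 60 markers found only in those lists, 1 reached 10% of that median in both PBS libraries and was lower in all treated libraries. Markers shared with other lists were left out of that count, among them the fibroblast marker Col1a2, which had no read in I80. The count therefore cannot decide whether such cells were present. PBS cultures that hold a share of at least 1% of cells with the profile of the treated lines are argued against by 9 genes under 1% of their treated level in both PBS libraries. A smaller share, and cells that took on that profile only under exposure, stay open. Lines of different origin or a relabelled culture cannot be told apart from long exposure without genotypes, the highest correlation between a PBS and a treated library being 0.827 (0.8269).

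Erbb2 was higher in both treated lines. A gain of most of the chromosomal region around Erbb2 is argued against. The median of its 40 nearest tested neighbours was at most -7.2% of its own log2 fold change. A few genes would hardly move that median, so a gain of Erbb2 alone or with a few neighbours stays open. Reads of the rat Neu transgene counted with mouse Erbb2 cannot be told apart in a table of genes. They could set any share of the 596.8 CPM in PBS and of the rise in the treated lines. A response to H2O2 stays open and untested.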
